A study of Aspergillus oryzae with 20 samples.

How the data were processed

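The series measured messenger RNA of Aspergillus oryzae, the filamentous fungus used for koji, in 4 strains derived from strain RIB40: a deletion control, strains lacking admA or admB, and a strain lacking both, all labelled as carrying pyrG and ligD. Each strain was sequenced in 5 libraries, 20 in all. Per the labels' protocols, 76.5 g of wheat bran medium with 70 mL of water per 100 g of bran was inoculated with conidia in a 1 L flask and kept at 30 °C for 72 h, and libraries were made from 4 µg of total RNA with a TruSeq kit. The labels do not say whether the 5 libraries of a strain came from separate flasks, so p-values measure the spread between these libraries, which may be technical.

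Per the file headers, the authors' deposited values are RPKM, reads scaled for the length of the gene model and for the mapped reads of the library. Per the submitters' processing notes, CASAVA 1.8.2, FastQC 0.10.1, TopHat2 2.0.9 and Cufflinks 2.1.1 were used; their roles and parameters, the genome build and the annotation are not given in the sources used here. Because the values are not counts, no count model was fitted. Each library lists 12074 genes. All 12074 identifiers matched locus tags of the RefSeq table of assembly ASM18445v3, which gives a symbol of its own to 714 of them; that table was used only for symbols and for the order of genes, and no coordinates are given. The symbols rest on that table alone. The identifier of admB is not paired with a symbol there, so admB itself was not analysed here.

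The depth in reads is unknown. Relative depth was read from genes with a mean below 1.5 RPKM, whose values step in whole reads: the ratios between 2 libraries form sharp clusters, the most filled of which was taken as the ratio of their depths. A cluster a factor of 2 away was about as filled for some libraries (54 and 54 genes in control replicate 2, 54 and 51 in double deletion replicate 2, 51 and 46 in admB deletion replicate 4), so their depths may be off by that factor. Against the shallowest library, estimated depth ranged from 1.00 to 2.15 times. Mean relative depth per strain was 1.35 ± 0.46 (SD, n = 5) in the control, 1.32 ± 0.26 in the admA deletion, 1.59 ± 0.20 in the admB deletion and 1.40 ± 0.42 in the double deletion. The same ratios divided the libraries into 2 sets. Within a set, 91.5% to 100.0% of the ratios near the cluster lay within 0.00015 log units of it, and between sets 5.8% to 25.0% did. Set 1 held 12 libraries (2 control, 3 admA deletion, 4 admB deletion, 3 double deletion) and set 2 held 8 (3, 2, 1 and 2). The sets were found from step sizes, not from expression levels, and their origin is not given in the sources used here.

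Genes with at least 1 RPKM in at least 5 of the 20 libraries were tested, 10652 in all, of which 702 had a symbol. Values were used as log2(RPKM + 1), and fold changes are on this scale, which understates the change of low genes. One mean per strain was fitted to all 20 libraries with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, no block), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values are from this limma test unless another test is named. The 6 contrasts were each deletion strain against the control, the double deletion against each single deletion, and the interaction, the double minus admA deletion less the admB deletion minus control. Single values were compared with exact permutation tests or, with 10 libraries on each side, permutation tests of 100000 resamples in scipy 1.17.1. Gene groups were tested with camera at a preset correlation of 0.01 between genes, with adjustment over groups within a contrast.

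Groups, contrasts, tests, the filter, the rule for named genes and most alternatives were fixed before the data were examined. The rule took admA, admB and pyrG; the 8 largest rises and 8 largest falls among genes past the threshold whose 5 values lay outside the 5 of the control; up to 2 rises and 2 falls per gene group among members past the threshold; and genes of fixed locus tags, of which the reference table bore out pyrG, ags1, ags3 and pksP. Of genes without a symbol, at most 2 that rose and 2 that fell are printed. Gene groups planned from protein motifs or product words could not be built from a table of symbols. They were replaced by 20 groups of symbols, plus the 10 genes nearest admA in reference order; 20 of these 21 groups had at least 5 tested members. The symbol groups were written after the table and the levels of a few genes (such as brlA, wetA, flbA, pksP and the ags and chs genes) had been seen, but before any test. In a group called by camera without members past the threshold, the members named were chosen after their values were seen, as were the symbol-bearing calls between the double and admA deletions. Library set as a covariate, each set alone, and the other alternatives named as such were also chosen after seeing the data.

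The fit was tested on simulated data with the real means and spreads of 10652 genes, of which 100 were changed by 1 log2 unit and 100 by 2. For the admA deletion against the control, 67 of 100 genes changed by 2 log2 units and 31 of 100 changed by 1 were called, all in the right direction, with 5 false calls. For the interaction the fit called 46 of 100 and 9 of 100. The simulated spread was independent between genes, unlike the real one.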

Results

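The data were the RPKM values of 12074 genes in 20 libraries of A. oryzae grown on wheat bran, 5 each from the deletion control, the admA deletion (ΔadmA), the admB deletion (ΔadmB) and the double deletion (ΔadmAΔadmB). The deleted genes encode proteins of the ADAM family, membrane-anchored metalloproteases. The sum of RPKM per library ranged from 3974009 to 5401733, 655 to 1260 genes were listed at 0, and relative depth, uncertain by a factor of 2 for some libraries, spanned an estimated 2.15 times. Log2 values of libraries of one strain correlated, across genes, at 0.79 to 0.934. The 20 most abundant genes made up between 17.8% and 34.5% of a library's RPKM sum.

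In the libraries labelled as lacking it, admA (AO090138000114) was listed at 0 in all 5 ΔadmAΔadmB libraries and in 4 of the 5 ΔadmA libraries, with 0.09 RPKM in ΔadmA replicate 4. In the strains that keep the gene it was also low: 0.25, 0.10, 0, 0.13 and 14.24 RPKM in control replicates 1 to 5, and 0.26, 0.21, 0.43, 3.42 and 1.05 RPKM in ΔadmB replicates 1 to 5. It lay above 0 in 9 of 10 libraries that keep it and in 1 of 10 that lack it (Fisher's exact test, two-sided, p = 0.0011). The mean log2(RPKM + 1) differed by 0.87 between these groups of 10 (two-sided permutation test, p = 0.00022), and by 0.54 without control replicate 5, since the other 4 controls lay at 0 to 0.25 RPKM. By two-sided exact permutation tests with n = 5 the difference was 0.89 between control and ΔadmA (p = 0.048) and 0.86 between ΔadmB and ΔadmAΔadmB (p = 0.0079). Without control replicate 5 the difference between control and ΔadmA was 0.13 and no longer passed (exact permutation test, p = 0.095), a test chosen after the values were seen. pyrG (AO090011000868), the orotidine 5'-phosphate decarboxylase gene that the labels of all strains name, was present in every library, at 37.3 ± 17.8 RPKM (SD, n = 5) in the control, 27.1 ± 19.4 in ΔadmA, 39.5 ± 14.8 in ΔadmB and 33.1 ± 16.0 in ΔadmAΔadmB. Its log2 differences from the control, -0.44, 0.22 and -0.07, did not pass the test (adjusted p = 0.88, 0.92 and 1), and it was lowest, at 6.83 RPKM, in control replicate 5.

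The comparison of ΔadmA with the control asks what loss of admA alone changes. The gene erg5 (AO090003000954), with the symbol of the sterol C-22 desaturase of ergosterol synthesis, rose from 4.57 ± 5.87 RPKM (SD, n = 5) to 194 ± 126, a log2 fold change of 5.44 (SE 1.13, adjusted p = 0.024). The gene vtc4 (AO090011000795), with the symbol of the polyphosphate polymerase of the vacuolar transporter chaperone complex, fell from 203 ± 63.0 to 64.9 ± 15.2 RPKM, a log2 fold change of -1.62 (SE 0.29, adjusted p = 0.013), and was lower in each of the 5 libraries than in any control. The gene gliK (AO090001000030), named after the gliotoxin cluster of a related species, rose from 1.09 ± 0.597 to 3.33 ± 1.28 RPKM, by 1.04 on the log2 scale (adjusted p = 0.037). These 3 were the genes with a symbol among 115 past the threshold.

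Of the 115 genes, 52 were higher and 63 lower in ΔadmA, 102 of them by at least 1 log2 unit, and in 73 the 5 ΔadmA values lay outside the range of the control values. Over all tested genes that share was 2.0%, against 0.79% by chance. Without a symbol, AO090001000045 was at 1.27 to 70.59 RPKM in the 5 ΔadmA libraries and at 0.37 or below in each of the other 15, a log2 fold change of 4.36 against the control (SE 0.61, adjusted p = 0.0046). AO090020000656 rose from 5.24 ± 2.07 to 432 ± 372 RPKM (log2 fold change 5.30, SE 1.17, adjusted p = 0.035). AO090023000804 fell from 2700 ± 1560 to 196 ± 212 RPKM (log2 fold change -4.33, SE 0.77, adjusted p = 0.013), and AO090010000351 from 52.7 ± 34.2 to 3.28 ± 5.03 RPKM (log2 fold change -4.08, SE 0.78, adjusted p = 0.016). In erg5 (replicates 3 and 5), AO090001000045 (replicates 2 and 3) and AO090020000656 (replicate 3), single ΔadmA libraries exceeded the gene's median over all 20 by more than 5 log2 units.

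None of the 20 tested gene groups was called in ΔadmA. In chitin synthesis, 9 of 11 members had a positive difference (median 0.14, camera adjusted p = 0.83). All 8 members of cell wall integrity signalling had one (median 0.31, adjusted p = 0.13). Of 20 genes of glucan synthesis and remodelling 8 did (median -0.13, adjusted p = 0.89), and of 19 of plant polysaccharide degradation 11 did (median 0.20, mean -0.02, which differ in sign, adjusted p = 0.94). The alpha-1,3-glucan synthase genes ags1 and ags3 differed by 0.81 (adjusted p = 0.78) and -0.73 (adjusted p = 0.45), and the conidial pigment polyketide synthase gene pksP by -0.03 (adjusted p = 0.99). Secondary metabolism had 1 of 21 members past the threshold, gliK, and 4 rises and 3 falls adjusted over the list alone (median -0.19, mean 0.32, which differ in sign, adjusted p = 0.83). Ergosterol synthesis had erg5 alone among 17 members, also adjusted over the list alone (adjusted p = 0.54). The other 14 groups had adjusted p-values of 0.48 to 1.

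The call of erg5 was lost in 10 of 34 alternatives (log2 fold change 4.92 to 6.71, adjusted p = 0.0037 to 0.92), that of gliK in 14 of 33 (0.89 to 1.58, adjusted p = 0.0049 to 1) and that of vtc4 in 3 of 34 (-1.93 to -1.36, adjusted p = 0.0025 to 0.87). Those of AO090020000656, AO090010000351, AO090023000804 and AO090001000045 were lost in 11, 4, 3 and 2 alternatives, with log2 fold changes of 4.30 to 6.94, -5.78 to -2.34, -4.89 to -3.84 and 3.18 to 7.07. With the spread taken from only the 10 libraries compared, 2 genes passed, 1 of them from the 115. Within library set 1, 3 genes passed, 1 of them from the 115, and within set 2, 36 passed, 11 of them from the 115. With library set as a covariate 113 passed, 104 of them from the 115. A filter at a mean of 10 RPKM gave 68 genes, sample quality weights 686 and the first principal component as a covariate 357. All 115 kept their direction within both sets, although they had been chosen on the same libraries. Leaving out ΔadmA replicate 1 gave 307 genes and without ΔadmA replicates 2 to 5 the counts were 70, 24, 58 and 34; leaving out control replicates 1 to 4 gave 73, 68, 64 and 57.

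**Figure D1:**
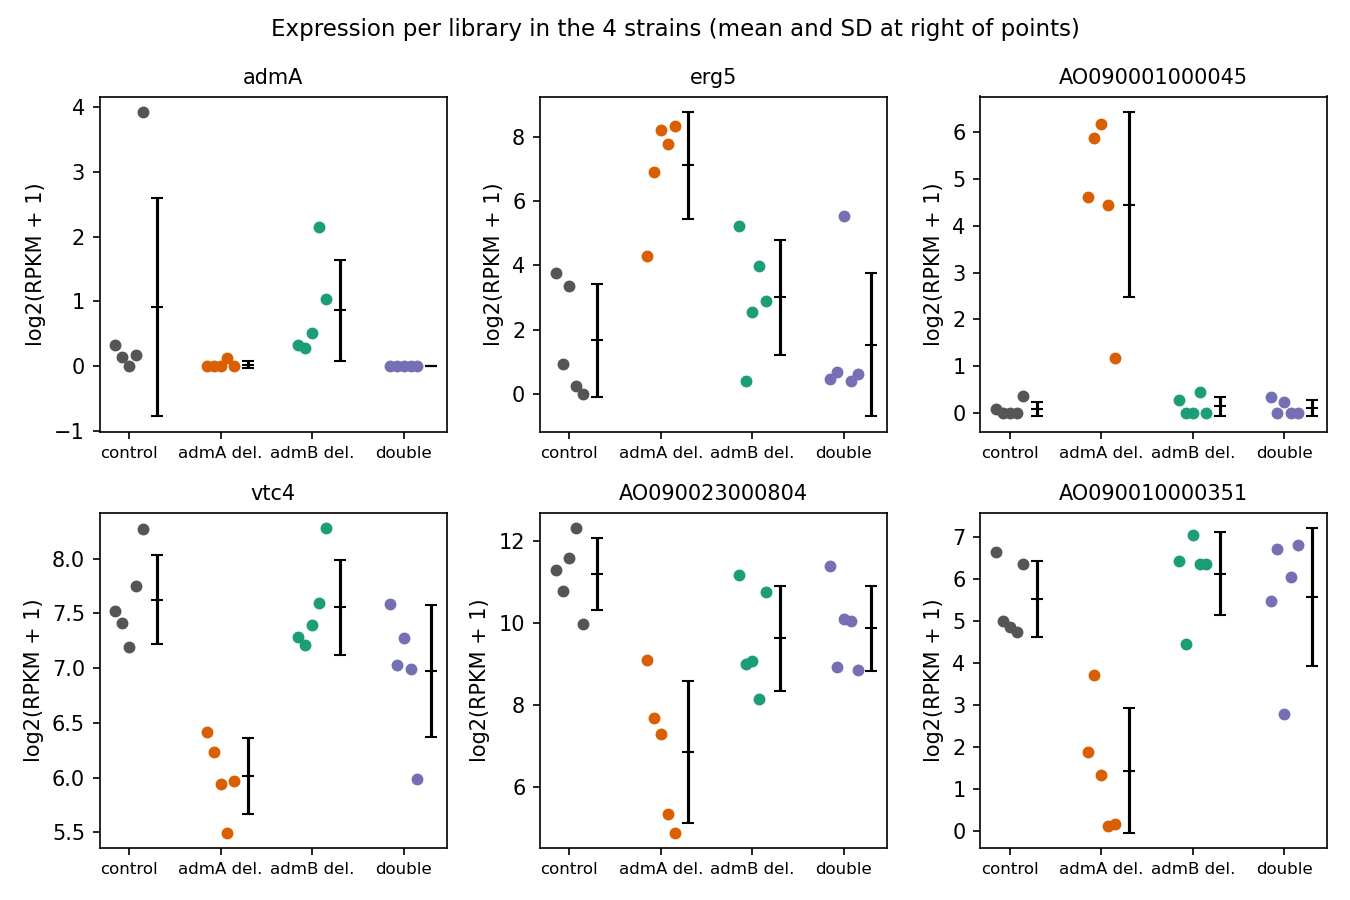
Expression as log2(RPKM + 1) in each library (points), with the mean and SD of 5 libraries at the right of each strain, for admA and 5 genes called in ΔadmA. AO090001000045 lies at 1.27 to 70.59 RPKM in ΔadmA and at 0.37 RPKM or below in the other 15 libraries, while vtc4 is lower in all 5 ΔadmA libraries than in any control.

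The comparison of ΔadmB with the control asks what loss of admB alone changes. No single gene passed the threshold. Genes of translation (ribosomal proteins and initiation factors) were higher as a group, with 10 of 13 members positive and a median log2 difference of 0.38 (camera adjusted p = 0.0062). The ribosomal protein gene rpl17 was at 5310 ± 915 RPKM (SD, n = 5) against 3770 ± 586 in the control, a log2 difference of 0.49 (SE 0.16, adjusted p = 0.59). Its ΔadmB replicate 1, at 3808 RPKM, lay within the control range of 3211 to 4715. The members EifCb and tif1 rested on single ΔadmB libraries. EifCb was at 3726 RPKM in replicate 1 and at most 446 in the others, and tif1 at 61963 in replicate 4 and at most 1122 in the others. Genes of autophagy were lower, 5 of 5 negative with a median of -0.64 (camera adjusted p = 0.012), as were those of conidiation, 12 of 14 negative with a median of -0.53 (camera adjusted p = 0.028). With an estimated correlation between genes these calls were lost, at adjusted p = 0.45 for translation (0.0055 to 0.45 over 8 alternatives), adjusted p = 0.61 for autophagy (0.0061 to 0.61) and adjusted p = 0.61 for conidiation (0.0061 to 0.61). The strains also differed in place on the first principal component. ΔadmB replicates 1 to 5 scored -59.6, 5.0, 13.4, 94.4 and 21.1, and control replicates 1 to 5 scored -62.5, -28.7, -67.3, -50.6 and 83.7. That component was used as a covariate only for ΔadmA against the control, so whether these group calls follow it was not tested.

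Among the autophagy genes, atg26, a sterol glucosyltransferase gene, was at 108 ± 38.6 RPKM in ΔadmB and 188 ± 47.4 in the control (log2 difference -0.84, adjusted p = 0.59), and the kinase gene atg1 at 211 ± 95.6 and 308 ± 43.8 (log2 difference -0.72, adjusted p = 0.64). In the conidiation group, brlA, the central regulator of conidiophore development, was at 6.71 ± 12.8 and 13.9 ± 19.0 RPKM (log2 difference -1.29, adjusted p = 0.74), with 29.68 RPKM in ΔadmB replicate 1 and at most 1.36 in the other 4, and 46.71 RPKM in control replicate 1. The pigment gene ayg1 was at 33.5 ± 71.9 and 166 ± 322 RPKM (log2 difference -1.66, adjusted p = 0.85), with 162.16 RPKM in ΔadmB replicate 4 and at most 1.6 in the other 4. The control mean of ayg1 likewise rested on replicates 5 and 3, at 738.13 and 87.11 RPKM, with at most 2.24 in the other 3. Without control replicate 5, which lay apart from the other controls on the first principal component, the median of conidiation was -0.58 and its adjusted p 0.058. Of the genes fixed by locus tag, ags1, ags3 and pksP differed by -0.44, 0.15 and 0.07 (adjusted p = 0.85, 0.91 and 0.96).

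In this contrast limma gave 864 genes at an unadjusted p under 0.05, where 533 would be expected by chance, and a smallest adjusted p of 0.595. With sample quality weights 746 genes passed, and leaving out ΔadmB replicate 1 gave 1. Within library set 1 2 genes passed and within set 2, with 1 ΔadmB library assumed to vary like the others, 11.

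The comparison of ΔadmAΔadmB with the control asks what loss of both genes changes. No gene and no gene group passed. The histone deacetylase gene hdaA (AO090003001321) was at 4200 ± 1180 RPKM (SD, n = 5) against 1490 ± 392, and each of the 5 values exceeded each control value (log2 difference 1.49, SE 0.29, adjusted p = 0.40). Over all tested genes, 0.6% had their 5 values all above or all below the control values, against 0.79% by chance. Of the genes called in ΔadmA, erg5 differed here by -0.13 (adjusted p = 1) and vtc4 by -0.65 (adjusted p = 0.97). AO090020000656 differed by 4.20 (adjusted p = 0.79) and AO090023000804 by -1.33 (adjusted p = 0.97), while AO090001000045 and AO090010000351 differed by 0.03 and 0.06. Of all 115 genes called in ΔadmA, 60 had the same sign here. The median ratio of the log2 difference here to that in ΔadmA was 0.02. At an unadjusted limma p under 0.05, 12 of the 115 passed with the same sign. Plant polysaccharide degradation had 12 of 19 members negative (median -0.46, camera adjusted p = 0.15), as had conidiation 12 of 14 (median -0.31, adjusted p = 0.15). Iron and siderophores had 3 of 12 members positive (median -0.37) and ribosome biogenesis 7 of 26 (median -0.20), each also at a camera adjusted p of 0.15. The differences of ags1, ags3 and pksP were -0.77, 0.19 and 0.05 (adjusted p = 0.99, 0.99 and 1).

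For this contrast limma gave 519 genes at an unadjusted p under 0.05, where 533 would be expected. Within library set 1 2 genes passed and within set 2 none did, and leaving out ΔadmAΔadmB replicate 3 gave 2.

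The comparison of ΔadmAΔadmB with ΔadmA asks what loss of admB changes where admA is already absent. In ΔadmAΔadmB, erg5 was lower, at 45.13 RPKM in replicate 3 and at most 0.59 in the other 4 against 194 ± 126 (SD, n = 5) in ΔadmA (log2 fold change -5.57, SE 1.13, adjusted p = 0.015). The gene hdaA was higher, at 4200 ± 1180 against 1640 ± 510 RPKM (log2 fold change 1.37, SE 0.29, adjusted p = 0.019). The gene prm1 (AO090003001100), with the symbol of a plasma membrane fusion protein, was lower, at 10.6 ± 1.81 against 31.5 ± 12.6 RPKM (log2 fold change -1.37, SE 0.30, adjusted p = 0.02), although ΔadmA replicate 1 was at 10.96 RPKM. The gene fmaF (AO090010000026), named after the fumagillin cluster of a related species, was lower, at 59.6 ± 56.4 against 242 ± 140 RPKM (log2 fold change -2.41, SE 0.60, adjusted p = 0.047). In ΔadmB against the control, hdaA, prm1 and fmaF differed in the same directions, by 0.79, -0.76 and -1.29 (adjusted p = 0.60, 0.61 and 0.61). There erg5 differed the other way, by 1.34 (adjusted p = 0.74). None of these genes passed for the interaction, so their changes are not shown to depend on the absence of admA.

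In all, 189 genes passed, 89 higher and 100 lower in the double deletion, and these 4 carried symbols. Of the 189, 84 were also among the 115 of ΔadmA against the control, each with the opposite sign; both comparisons use the same ΔadmA libraries with opposite sign, which favours such sharing without any further effect. No gene group was called. The call of fmaF was lost in 20 of 33 alternatives (log2 fold change -2.86 to -1.75, adjusted p = 0.0071 to 0.55), and those of prm1, hdaA and erg5 in 10, 7 and 3 (-1.70 to -1.22, 1.23 to 1.53 and -6.69 to -4.46). A filter at a mean of 10 RPKM gave 122 genes and sample quality weights 411. With only the 10 libraries compared 1 gene passed, 2 within library set 1 and 7 within set 2, of which 1, 2 and 2 were from the 189. Leaving out 1 library gave 307 genes without ΔadmA replicate 1, 98, 109 and 110 without ΔadmA replicates 3 to 5, and 101, 108 and 112 without ΔadmAΔadmB replicates 2, 4 and 5.

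The comparison of ΔadmAΔadmB with ΔadmB asks what loss of admA changes where admB is already absent. No single gene passed. Genes of translation were lower as a group, 10 of 13 negative with a median of -0.46 (camera adjusted p = 0.00023), as were genes of ribosome biogenesis, 23 of 26 negative with a median of -0.42 (camera adjusted p = 0.00023). Autophagy genes were higher, 5 of 5 positive with a median of 0.53 (camera adjusted p = 0.0053). With an estimated correlation the calls were lost, at adjusted p = 0.17 for translation (0.00019 to 0.17 over 8 alternatives), adjusted p = 0.73 for ribosome biogenesis (0.00019 to 0.73) and adjusted p = 0.60 for autophagy (0.0015 to 0.60). The ribosomal protein gene rpL3 was at 1910 ± 486 RPKM (SD, n = 5) against 2980 ± 565 (log2 difference -0.65, adjusted p = 0.80), and cbf5, the pseudouridine synthase gene of ribosomal RNA processing, at 962 ± 555, with 1949 in replicate 5, against 1910 ± 1130, with 3856 in ΔadmB replicate 4 and at most 1842 in the other 4 (log2 difference -0.97, adjusted p = 0.81). The group calls here and those of ΔadmB against the control use the same ΔadmB libraries with opposite sign. This favours mirrored differences without any further effect of admA, so the calls are not independent. In ΔadmAΔadmB against the control, medians were -0.02 for translation and -0.11 for autophagy (camera adjusted p = 0.99 for each). Ribosome biogenesis had a median of -0.20 there (camera adjusted p = 0.15). Limma gave 612 genes at an unadjusted p under 0.05, with 533 expected. Leaving out ΔadmB replicate 1 gave 1 gene; within library set 1 none passed and within set 2, with 1 ΔadmB library assumed to vary like the others, 8 did.

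The interaction asks whether the effect of the admB deletion differs with admA present or absent. No gene passed, and the smallest adjusted p was 0.124. For erg5 the interaction was -6.91 on the log2 scale (SE 1.60, adjusted p = 0.23), for AO090001000045 -4.39 (SE 0.86, adjusted p = 0.12) and for vtc4 1.04 (SE 0.41, adjusted p = 0.69). Translation was the group called, 11 of 13 members negative with a median of -0.55 (camera adjusted p = 0.0041). With an estimated correlation its camera adjusted p was 0.39 (0.0036 to 0.39 over 8 alternatives). This call draws on the same ΔadmB libraries as the translation calls of ΔadmB against the control and of ΔadmAΔadmB against ΔadmB, so it is not independent of them. Of the 115 genes called in ΔadmA, all 115 had an interaction of the opposite sign and 101 passed it adjusted over the list alone, which is not independent evidence since they were chosen on the same libraries. Limma gave 693 genes at an unadjusted p under 0.05, with 533 expected. Leaving out ΔadmA replicate 1 gave 66 genes and leaving out ΔadmA replicate 5 gave 1; sample quality weights gave 67, library set as a covariate 3, set 1 alone 1 and set 2 alone, with its 1 ΔadmB library, 5.

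The log2 fold changes against the control correlated across genes at 0.32 for ΔadmA and ΔadmB, 0.42 for ΔadmA and ΔadmAΔadmB, and 0.59 for ΔadmB and ΔadmAΔadmB. Unchanged groups simulated against the same controls gave 0.50 for each pair. The covariances were 0.176, 0.208 and 0.272, against simulated values of 0.214, 0.214 and 0.215. With the controls split 2 and 3 between the comparisons, the median correlation over 10 splits was -0.02, 0.00 and 0.07. Genes are not independent replicates. Since ΔadmB and ΔadmAΔadmB had no called genes, there was no overlap of calls to count.

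**Figure D2:**
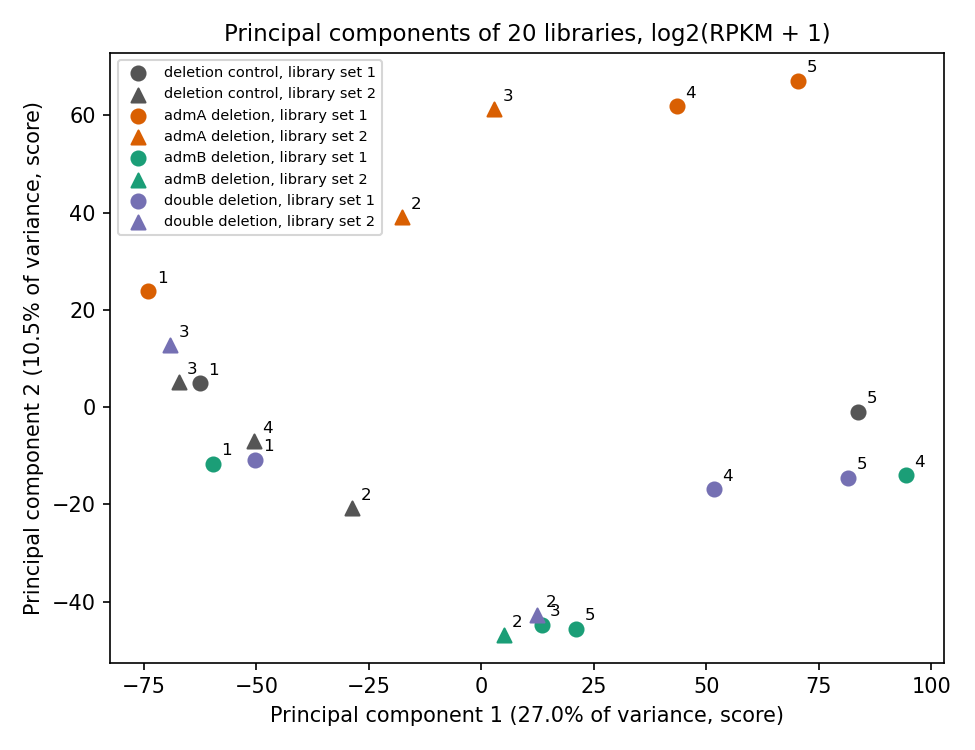
Scores of the 20 libraries on the first 2 principal components of log2(RPKM + 1) of 10652 genes (27.0% and 10.5% of the variance), coloured by strain, with replicate numbers beside the points and symbols for the 2 library sets. The first component spreads libraries within each strain, with control replicate 5 at 83.7 and the other controls between -67.3 and -28.7, and on the second the 5 ΔadmA libraries have the highest scores.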

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

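Library set and the first component as covariates, the tests of neighbouring genes and of swapped labels, the added permutation over libraries, and the test of genes that part the library sets were chosen after the results were seen. Of 100 groups of 5 libraries (25 named genes in 4 strains), 19 held a library far from the other 4 by the ratio of its gap to the range; chance gives about 1 in 20 for genes not chosen by their values, which does not hold for part of these genes. Among these genes tif1 and EifCb belong to the translation group.

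In the control, replicate 5 was high for admA (ratio 0.92, 14.24 RPKM), tif1 (ratio 0.86, 13646 RPKM) and AO090001000045 (ratio 0.77, 0.29 RPKM) and low for pyrG (ratio 0.83, 6.83 RPKM). In ΔadmA, replicate 1 was high for brlA (ratio 0.85, 90.16 RPKM) and low for prm1 (ratio 0.76, 10.96 RPKM) and ags1 (ratio 0.73, 6.57 RPKM), replicate 2 was high for rpl17 (ratio 0.72), and replicate 4 alone had admA above 0 (ratio 1.0). In ΔadmB, replicate 1 was high for brlA (ratio 0.85, 29.68 RPKM) and EifCb (ratio 0.96, 3726 RPKM), replicate 2 was low for AO090010000351 (ratio 0.74, 20.78 RPKM), and replicate 4 was low for pyrG (ratio 0.74) and high for ayg1 (ratio 0.93, 162 RPKM) and tif1 (ratio 0.96, 61963 RPKM). In ΔadmAΔadmB, replicate 1 was high for EifCb (ratio 0.86, 1452 RPKM), replicate 3 for erg5 (ratio 0.95, 45.13 RPKM), and replicate 5 for tif1 (ratio 0.82, 11345 RPKM) and cbf5 (ratio 0.83, 1949 RPKM). Some of these libraries lay at the ends of the first principal component. Control replicate 5 and ΔadmB replicate 4, both high for tif1 and low for pyrG, had its highest scores, 83.7 and 94.4. ΔadmA replicate 1 and ΔadmB replicate 1, both high for brlA, scored -74.0 and -59.6. Whether the flagged values follow this component was not tested. The effect of the admB deletion on translation genes differed with and without admA by a median of -0.55 (camera adjusted p = 0.0041, lost with an estimated correlation at adjusted p = 0.39).

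The 115 genes of ΔadmA against the control form the first pattern. Of 100 splits of the 10 libraries, the real one included, 2 gave as many genes. That share lies under 0.05 only if the libraries are independent, and it is not adjusted over the contrasts. Chance differences between cultures are therefore not excluded. The highest other split gave 1020 genes, several times the real count, which points to a structure of the libraries. It exchanged control replicate 5 and ΔadmA replicate 1, at 83.7 and -74.0 on the first principal component. With set as a covariate 104 of the 115 passed, and 115 of 115 did with the first component of the other genes. This argues against library set and that gradient as the main source, but only weakly. The genes had been chosen on the same libraries, and the sets are nearly balanced (2 control and 3 ΔadmA libraries in set 1, 3 and 2 in set 2). Exchanged labels are argued against by admA at 14.24 RPKM in control replicate 5, where the ΔadmA libraries had at most 0.09. This rests on 1 library. The 0 in ΔadmA replicate 1 cannot decide, since control replicate 3 was also at 0. An effect of admA that the second deletion offsets and an unplanned change in this 1 strain both stay open, and the interaction, with 0 genes past the threshold, does not establish the first. Against the first stands that control replicates 1 to 4 held admA at only 0 to 0.25 RPKM, so the deletion removed little messenger RNA at 72 h. Earlier times were not measured.

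The second pattern is 3 genes, singled out after their values were seen, that part the library sets. AO090023000612 was at 2514 to 32236 RPKM in the 12 libraries of set 1 and at 1.9 to 3.1 in the 8 of set 2, AO090012000517 at 1884 to 37297 and 10.4 to 15.8, and AO090003000005 at 21797 to 155920 and 332.3 to 664.8. None of 99 other random divisions into 12 and 8 parted any gene by more than 4 log2 units, against 3 here, which a difference in preparation or processing between the sets could produce. Reads moved from the adjacent genes would lower those, which differed by a median of -0.09 log2 units. Every strain is in both sets, so strain does not explain it, and no other biological explanation was tested.

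The third pattern is single genes far above their level in other libraries: 743 cases in 475 genes in which 1 to 3 libraries exceeded the gene's median by over 5 log2 units, among them 2 ΔadmA libraries of erg5, 2 of AO090001000045 and 1 of AO090020000656. Reads or regulation shared with neighbours as the whole cause is argued against by the adjacent genes, whose median deviation in the same library was 0.39 log2 units (0.31 over all genes), but it stays open for part of the cases, since 25.4% of the 1486 adjacent genes deviated by over 1 log2 unit. Set 1 held 65.3% of the cases with 60% of the libraries (exact binomial p = 0.0035), but cases in a library are not independent, and permuting libraries gave p = 0.08, so whether the sets differ stays open. The 258 cases in set 2 show that set 1 alone is not the source. No biological explanation other than regulation shared with neighbours was tested.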

How the results depend on the processing

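Library set as a covariate, each set alone, the block with set, the first component as a covariate and the gene groups without control replicate 5 were chosen after seeing the data. DESeq2 was planned only for counts and was not run, and filters do not apply to the admA value; the fit with 2 groups does not apply to the interaction. The admA difference between the 10 libraries with and the 10 without the gene kept its direction and call under all 24 alternatives run (0.54, without control replicate 5, to 2.48).

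For ΔadmA against control, 115 genes became 68 with a mean of at least 10 RPKM (8457 genes tested), 2 with only the 2 groups (fewer samples for the spread), 686 with sample quality weights, 357 with the first component, 3 in set 1 and 36 in set 2; other settings gave 103 to 144 apart from the block. For ΔadmAΔadmB against ΔadmA, 189 became 122, 1, 411, 2 and 7 under the same filter, groups, weights and sets, and 313 with block and set. Sample quality weights gave 746 genes for ΔadmB and 67 for the interaction, from 0. Sets 1 and 2 gave 2 and 11 for ΔadmB, set 1 gave 2 for ΔadmAΔadmB against control, set 2 gave 8 for ΔadmAΔadmB against ΔadmB, and the interaction had 1 and 5, and 3 with set as a covariate. The cause of these changes, the smaller sample numbers included, was not tested.

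Leaving out 1 library gave 24 to 307 genes for ΔadmA against control, 0 to 1 for ΔadmB, 0 to 2 for ΔadmAΔadmB, 98 to 307 for ΔadmAΔadmB against ΔadmA, 0 to 1 against ΔadmB and 0 to 66 for the interaction. The replicate block gave 201 genes for ΔadmA against control and 289 for ΔadmAΔadmB against ΔadmA, and 0 for the other 4. Same-numbered libraries did not all deviate together. Their correlations were 0.24 to 0.44 for number 1, 0.11 to 0.21 for number 2 and -0.06 to 0.35 for number 3. For number 4 they were -0.22 to 0.30 and for number 5 0.03 to 0.52. The numbers are therefore not taken to pair the libraries. Yet 11 of 20 correlated best with their own number, where chance gives about 1 in 5. On the first principal component, number 1 lay at -74.0 to -50.4 and number 5 at 21.1 to 83.7 over all strains. Libraries of these numbers thus shared a position across strains, which the main fit without a block does not model.

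Of 7 group calls, 0 held with an estimated correlation and fry, a different test, called 1 (translation, ΔadmAΔadmB against ΔadmB); all 7 held with the block, both normalizations and a pseudocount of 0.1. Splitting the controls brought the correlations of 0.32, 0.42 and 0.59 to -0.02, 0.00 and 0.07. For named genes, 649 of the alternative values kept direction and the presence or absence of a call, 180 lost the call and 10 changed sign without a call. The 649 include values of pyrG, which had no call to keep: 33 in ΔadmA, 32 in ΔadmB and 25 in ΔadmAΔadmB against the control. All sign changes were in pyrG, and all lost calls were in the other genes. Of 100 splits of the libraries for ΔadmAΔadmB against ΔadmA, 1, the real one, gave 189 genes (highest other 135). This share is under 0.05 for libraries taken as independent, without adjustment over the contrasts. It does not exclude chance differences between cultures. Where the real count was 0, all 100 splits reach it by construction and test nothing; the highest gave 777 for ΔadmB, 3 for ΔadmAΔadmB, 2 for ΔadmAΔadmB against ΔadmB and 2359 for the interaction, of which 777 and 2359 point to a structure of the libraries. Unknown read depth leaves genes near 1 RPKM without a counting interval.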

Other observations

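The test of places along the chromosomes and of genes outside long runs was chosen after the results were seen. The genes that differed between ΔadmA and the control lay near each other more often than random genes. Of the 115, 43 had another called gene within 3 genes in the reference order, against a median of 6 and a highest value of 24 in 10000 random draws of as many tested genes (permutation test, p = 1e-04, the smallest such draws can give). They formed 20 runs, each of which moved in 1 direction. A hypothesis from this count is that some neighbouring genes may change together. The count was not compared with other splits of the libraries, so it cannot tie such changes to this strain. The secondary metabolism group had 1 of 21 members called (camera adjusted p = 0.83).

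A change in copy number of a chromosome segment is a candidate explanation for part of this. The largest median log2 fold change over 51 neighbouring tested genes was 0.66, at the first 51 tested genes of chromosome 2, where 39 were positive and the quartiles were 0.13 and 1.67. This passed the 0.5 set before the test, but 13 of 99 other splits of the libraries gave a run as far from 0 (highest 0.91), so the run cannot be told apart from the structure of the libraries. Its median against the control mean was 0.97, 0.91, 0.47 and 0.95 in ΔadmA replicates 2 to 5 and -0.20 in replicate 1, and 0.45 in control replicate 5. Such a segment could not hold most of the calls, since 108 of the 115 lay outside runs of at least 0.5, and medians of whole chromosomes lay between -0.03 and 0.01.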
